A study of Mus musculus with 14 samples.

How the data were processed

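Polyadenylated RNA from 14 libraries of mouse intestinal stem cells, sorted for EGFP from the Lgr5 locus, was sequenced as strand-specific TruSeq libraries. Per the labels, RNA was extracted with Trizol and 1 µg of total RNA entered each library. The deposited tables hold raw counts per Ensembl gene, as whole numbers with no normalization, in 1 table for the 8 libraries of the Chrm3 experiment and another for the 6 libraries of the ageing experiment. The submitters' notes name the mm10 genome and FastQC 0.11.2. The aligner, the counting tool and its settings are not given in the sources used here. Each table holds 55335 genes, of which 55154 have an identifier in GENCODE release M21, from which all gene positions were taken.

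The groups were WT NT, WT ES, KO NT and KO ES with n = 2 each, and young and old with n = 3 each. In the count table the NT libraries carry the name Ctrl, which was read as NT because both names mark the libraries without ES. The labels do not say whether each library came from a different animal, so the p-values measure the spread between these libraries. The 2 tables were normalised and tested separately, and no library of one was tested against a library of the other.

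Genes were kept with the default settings of the filterByExpr function of edgeR, counts were scaled with trimmed mean of M-values (TMM) factors, and a quasi-likelihood model with one mean per group was fitted in edgeR 4.0.16. All 8 libraries of the Chrm3 table shared one estimate of the spread. The comparisons were ES against NT in WT, ES against NT in KO, KO against WT in NT, KO against WT in ES, the difference of the 2 ES effects (KO minus WT), and old against young. The p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes with an adjusted p under 0.05 are said to have risen or fallen. Fold changes are on the log2 scale. The ± after a log2 fold change is a standard error derived from that change and its quasi-likelihood F statistic, and is approximate. Levels are CPM after TMM scaling, and ± after a level is the standard deviation between libraries.

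A total of 37 gene lists for cell types and pathways were fixed before the data were examined, as were the comparisons, most of the alternatives and the rule for naming genes. The rule took the 8 genes with the largest change in each direction in ES in WT, in the difference of the ES effects and in old against young, and 4 in the other comparisons. Such genes passed the test, had a mean of at least 1 CPM, did not overlap between the groups and were not predicted genes. If fewer than 3 genes passed in a direction, the 3 with the smallest p were taken and are given as not passing. Up to 4 members by p were added from each list that passed its own test or had at least 2 passing members, with Chrm3, Lgr5, Olfm4, Ascl2, Mki67, Cdkn1a and Cdkn2a always included. Cdkn2a was removed by the count filter and was not tested. A few genes that the rule takes are not reported here. Other list members given as examples were picked from the passing ones after their values were seen.

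For each list the members that passed over all genes were counted, and the count was repeated with the p-values adjusted over the list alone. The 32 lists with at least 5 tested members were compared with all other genes by camera from limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 32 lists of a comparison. The test was repeated with an estimated correlation. The fry test was run as well, which asks whether a list changed at all and not whether it differs from other genes. Genes higher and genes lower in old were tested as sets in the 5 Chrm3 comparisons in the same way, adjusted over these 10 tests. Overlaps used Fisher's exact test, one-sided for an excess, over the genes tested in both tables. Calls per chromosome used the two-sided Fisher's exact test over chromosomes with at least 20 tested genes, adjusted over 126 tests. The odds ratios for chromosomes include a small constant added to each count. Intervals of list medians are 95% bootstrap intervals over members from 10000 draws.

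The fit was checked on simulated data built from these counts. With 200 genes changed, the ES in WT design found 68.7% of 1.5-fold, 97.0% of 2-fold and 100% of 4-fold changes, with 6.84% false calls. In the ageing design the shares were 85.1%, 98.5% and 100%, with 8.25% false calls. The changed genes were drawn only from those above a floor in CPM, and counts were drawn independently for each gene. The shares therefore do not cover genes with low counts or shifts common to a whole library. Alternatives were size factors by relative log expression (RLE), no count filter, a 1 CPM filter, the older form of the quasi-likelihood test, limma-voom, DESeq2 1.42.0, a term for the replicate number, stricter and looser thresholds, fitting only the 2 groups compared, and leaving out each library in turn. Leaving out chromosome 17, or 4 of the lists, was added after the results were seen. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.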

Results

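The data are RNA profiles of Lgr5-positive intestinal stem cells, the dividing cells at the base of the crypt that renew the gut epithelium. The series title ties long-lasting stress to the ageing of these cells. In the first experiment the mice carried a tamoxifen-inducible Cre recombinase in Lgr5 cells and a floxed Chrm3 gene, which encodes the M3 muscarinic acetylcholine receptor. Mice given vehicle are named WT and mice given tamoxifen KO, so that genotype and injection changed together, and the injection came 3 days before the procedure abbreviated ES. Each genotype had an NT and an ES group of n = 2. In the second experiment, mice with the Lgr5 reporter were 2 months old (young) or 18 months old (old), with n = 3 each. Total counts, in M, were 31.5 and 29.5 in WT NT, 30.6 and 26.7 in WT ES, 36.9 and 33.9 in KO NT, and 31.3 and 35.8 in KO ES. They were 32.9, 34.9 and 35.8 in young and 33.1, 35.6 and 32.4 in old. Mitochondrial genes took 8.74% of the counts in KO NT replicate 2 and 6.12% to 7.53% in the other libraries.

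Chrm3 (GRCm38 chromosome 13, 9875486 to 10360847) was counted in every library, KO included. It had 343 and 254 counts in KO NT against 355 and 386 in WT NT, a log2 fold change of -0.50 ± 0.16 that did not pass the test (adjusted p = 0.119). In ES it had 256 and 213 counts in KO against 357 and 291 in WT and fell by 0.68 on the log2 scale, with a standard error of 0.17 (adjusted p = 0.0363). That call was lost when either WT NT library, either WT ES library or KO ES replicate 2 was left out, with adjusted p from 0.0623 to 0.238. The deleted part of the gene is not given in the sources used here, so a count over the whole gene checks the KO label only weakly.

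The first comparison asked what ES changed in WT. Genes of goblet cells, which secrete the mucus layer, rose in WT. Muc2, the main gel-forming mucin, went from 476 ± 6.61 to 995 ± 31.6 CPM (n = 2 each, log2 fold change 1.06 ± 0.06, adjusted p = 3.02e-05). Clca1, a mucus-processing protein, went from 300.4 to 909 CPM (1.60 ± 0.09, adjusted p = 3.46e-05). Among stem cell genes, of which 15 of 28 fell, Lgr5, the receptor by which these cells are sorted, went from 131 ± 2.73 to 94.9 ± 5.90 CPM (-0.46 ± 0.08, adjusted p = 0.0152), and Ascl2, a transcription factor that maintains stem cell identity, from 36.0 and 37.2 to 22.1 and 21.9 CPM (-0.74 ± 0.10, adjusted p = 0.00685).

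Of the 20 tested goblet cell genes, 15 rose, none fell and 5 did not pass (18 rose adjusted over the list alone). Fcgbp rose by 0.96 ± 0.06, Agr2 by 0.82 ± 0.06 and Tff3 by 0.79 ± 0.06. This was the one list of the comparison whose test also passed with an estimated correlation (adjusted p = 0.00833, against 3.25e-66 with the preset one). Of 28 stem cell genes, 15 fell and 13 did not pass (23 fell adjusted over the list alone). Among them were Axin2 (-0.56 ± 0.06), Scn2b (-0.75 ± 0.08), Msi1 (-0.63 ± 0.07) and Olfm4 (-0.34 ± 0.07). The list's adjusted p was 3.66e-27, and 0.169 with an estimated correlation. Wnt target genes, which share 11 members with the stem cell list, had 4 of 19 lower (13 adjusted over the list alone), among them Rnf43 (-0.28 ± 0.06), with an adjusted p of 1.09e-11, and 0.207 with an estimated correlation.

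Antimicrobial and inflammatory genes of the epithelium rose in 9 of 16 cases (12 adjusted over the list alone). Reg3g, a bactericidal lectin, rose by 1.56 ± 0.21, Reg3b by 1.66 ± 0.31, and the cytokine Il18 by 1.08 ± 0.18. The list's adjusted p was 5.72e-16, and 0.0593 with an estimated correlation. Retnlb, a goblet cell protein found in both lists, rose by 3.50 ± 0.38, from 0.322 to 3.69 CPM, the largest rise among the named genes. Hormone genes of enteroendocrine cells rose in 4 of 24 cases (11 adjusted over the list alone), Gip by 1.18 ± 0.15 and Chga by 0.81 ± 0.12 (adjusted p = 0.169 for the list with an estimated correlation). Paneth cell genes rose in 6 of 20 cases (13 adjusted over the list alone), Mmp7 by 0.70 ± 0.07 and Ang4 by 0.55 ± 0.10 (adjusted p = 0.260 with an estimated correlation). Absorptive enterocyte genes rose in 4 of 27 cases (14 adjusted over the list alone), Alpi by 1.22 ± 0.22 and Krt20 by 0.85 ± 0.18 (adjusted p = 0.331 with an estimated correlation). Tuft cell genes had a median of 0.09, and edgeR passed 0 of 17 (2 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom).

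Interferon response genes rose in 7 of 45 cases (22 adjusted over the list alone), Ifit1bl1 by 1.45 ± 0.17 and Igtp by 0.77 ± 0.12 (adjusted p = 0.169 with an estimated correlation). Genes induced by glucocorticoids went both ways, with 4 of 18 higher and 2 lower (8 and 2 adjusted over the list alone). Zbtb16, a transcription factor, rose by 2.48 ± 0.36, Per1 by 0.90 ± 0.10 and Tsc22d3 by 0.55 ± 0.09, while the metallothioneins Mt1 (-0.75 ± 0.08) and Mt2 (-1.67 ± 0.26) fell, and the list's adjusted p was 0.00158, and 0.169 with an estimated correlation. Cell cycle genes split as well, with 7 higher, 4 lower and 26 not passing (16 and 11 adjusted over the list alone, adjusted p = 0.172 for the list). The mitotic genes Plk1 (0.42 ± 0.07) and Cdc20 (0.34 ± 0.06) rose, and the replication helicase genes Mcm4 (-0.37 ± 0.06) and Mcm2 (-0.32 ± 0.06) fell. Of 18 senescence genes edgeR passed 0 (3 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom), of 25 p53 targets 0 (4, 0 and 0 in the same order), and of 16 p38 pathway genes 0 (3, 0 and 1). Cdkn1a, a cell cycle inhibitor, had a log2 fold change of 0.30 ± 0.16 (adjusted p = 0.359), and Mki67, a proliferation marker, one of -0.00 ± 0.10 (adjusted p = 0.994).

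**Figure D1:**
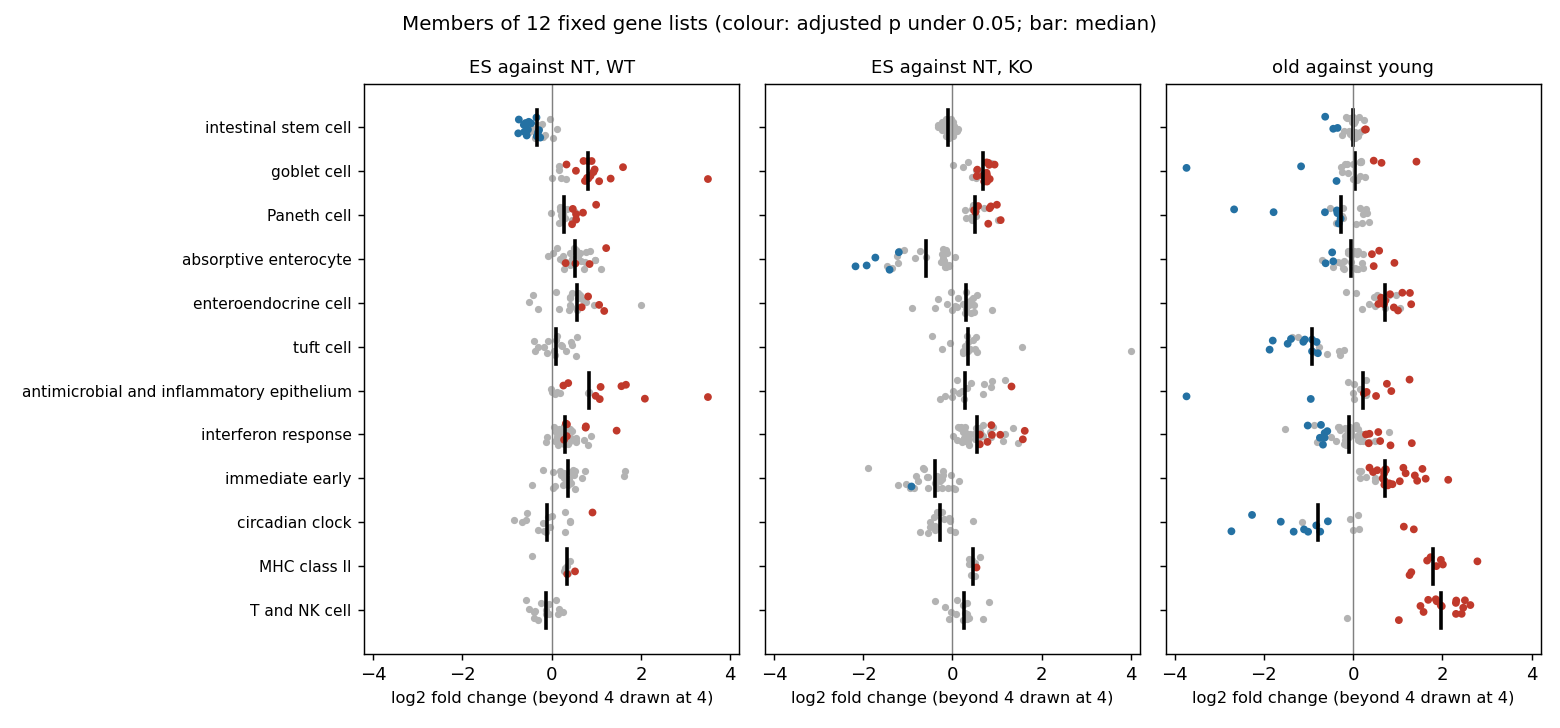
Log2 fold change of each member of 12 gene lists with ES in WT, with ES in KO and in old against young, with coloured points for adjusted p under 0.05 and a bar at the median. Goblet cell genes sit above 0 with ES in both genotypes, and T and NK cell and MHC class II genes lie furthest above 0 in old.

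Other large rises were those of the peptide transporter Slc15a2 (2.77 ± 0.29), Med12l (2.72 ± 0.45), Fhl1 (2.11 ± 0.37), the siderophore-binding protein Lcn2 (2.09 ± 0.43), the glycosyltransferase B3galt5 (1.92 ± 0.30) and the kinase Ptk6 (1.88 ± 0.28). The largest falls by the naming rule besides Mt2 were those of Raver1 (-2.97 ± 0.44), AC124739.5 (-1.76 ± 0.39), Fgfbp3 (-1.24 ± 0.27), Rec8 (-1.09 ± 0.15), Rassf10 (-1.06 ± 0.23), Dpysl5 (from 30.1 to 15.1 CPM) and Pcdh8 (-0.98 ± 0.21). Raver1 overlaps another identifier of the same symbol on the same strand, and its level also ran from 30.4 to 107 CPM between the KO NT libraries, so its count is uncertain. On GRCm38, Muc2 lies on chromosome 7 (141690340 to 141754693), Clca1 on chromosome 3 (145003817 to 145032776), Lgr5 on chromosome 10 (115450311 to 115587780), Ascl2 on chromosome 7 (142966829 to 142969264) and Retnlb on chromosome 16 (48816856 to 48818892).

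In all, 605 of 17364 genes changed with ES in WT, 364 higher and 241 lower, 86 of them at least 2-fold. The count fell without any of the WT libraries, where a library was left alone in its group and fewer calls follow by construction. That alone does not give the larger drop without a WT NT library than without a WT ES one. ES in KO also lost calls without a WT NT library, which is in neither of its groups. The WT NT pair was the most alike, with a chi-square per degree of freedom of 3.55. The value was 12.9 in WT ES, 14.5 in KO ES and 24.95 in KO NT. Whether this pair lowered the shared spread was not tested, and the labels do not say that its libraries came from different animals. The count for ES in WT rose without either KO NT library. These are in neither group compared and enter through the shared spread and the scaling. Of the 60 named genes that passed, 11 passed whichever library was left out, and none changed sign with a call.

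**Figure D2:**
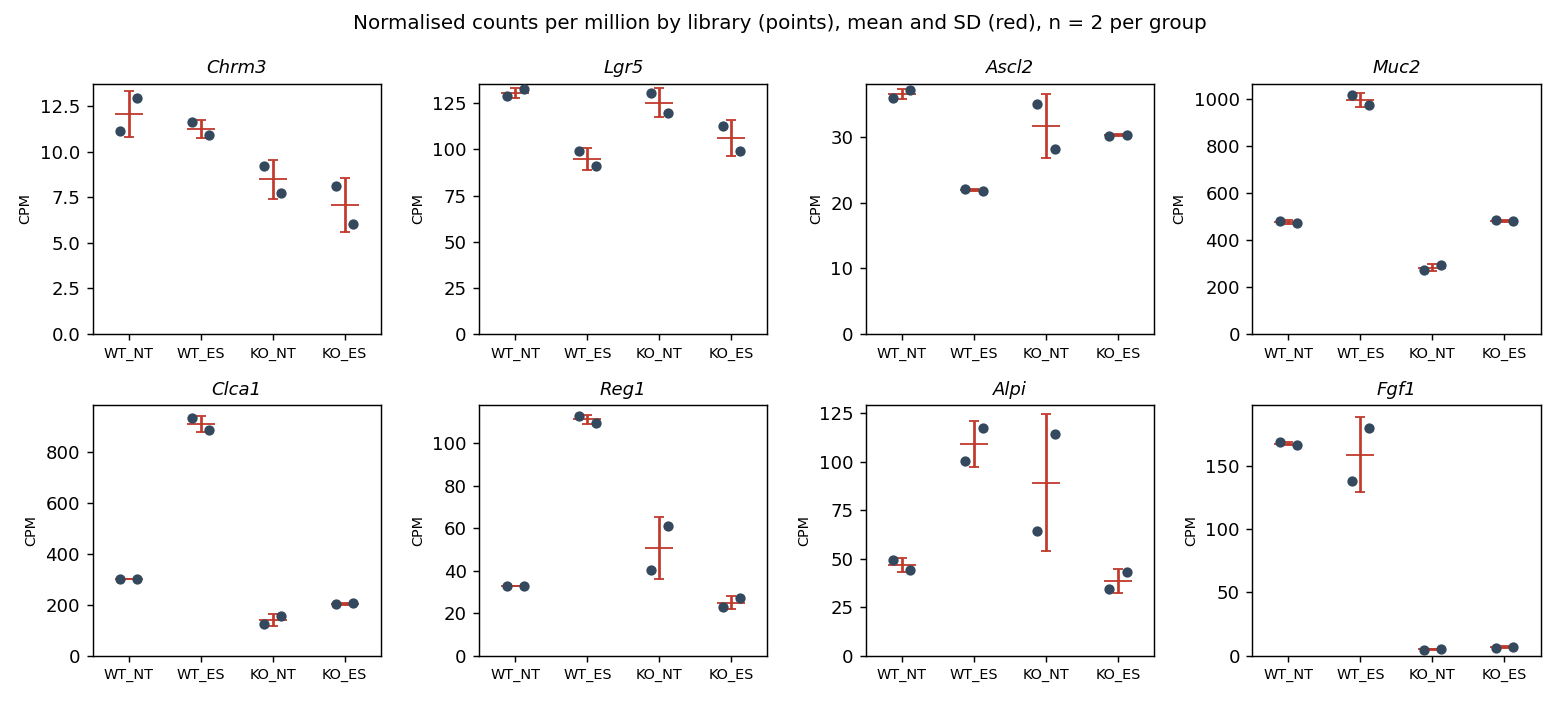
CPM of 8 genes in each library of the Chrm3 experiment, with mean and standard deviation (n = 2 per group). Muc2 is higher with ES in both genotypes, Reg1 and Alpi are higher with ES in WT and lower in KO, and Fgf1 is near 0 in KO.

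The next comparison asked what ES changed in KO. Goblet cell genes rose in KO as well, with 12 of 20 higher and none lower (18 adjusted over the list alone). Muc2 went from 282 ± 13.2 to 481 ± 2.73 CPM (n = 2 each, 0.77 ± 0.06), and Fcgbp (0.78 ± 0.06), Tff3 (0.77 ± 0.07) and Agr2 (0.68 ± 0.06) rose with it. The list also passed with an estimated correlation (adjusted p = 0.00609). Paneth cell genes rose in 8 of 20 cases (19 adjusted over the list alone), the pentraxin Mptx2 by 0.86 ± 0.06 and the protease Mmp7, which activates defensins, by 0.83 ± 0.07 (adjusted p = 0.0739 with an estimated correlation). Interferon response genes rose in 8 of 45 cases (31 adjusted over the list alone), Zbp1 by 1.62 ± 0.30, Gbp3 by 1.58 ± 0.25 and Oasl2 by 0.89 ± 0.13 (adjusted p = 0.0576 with an estimated correlation). Absorptive enterocyte genes fell in 5 of 27 cases (14 adjusted over the list alone), the lactase gene Lct by 1.73 on the log2 scale, Apoa4 by 1.92 and Alpi by 1.20 (adjusted p = 0.178 with an estimated correlation).

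For stem cell genes edgeR passed 0 of 28 in KO (9 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom). Lgr5 had a log2 fold change of -0.24 ± 0.08 (adjusted p = 0.346), Ascl2 one of -0.07 ± 0.10 (adjusted p = 0.948) and Olfm4 one of -0.10 ± 0.07 (adjusted p = 0.815). The list's median was -0.09 with an adjusted p of 0.000257, and 0.528 with an estimated correlation. Its direction turned without KO NT replicate 1 (adjusted p = 0.764) and the call was lost without KO ES replicate 2 (0.0945). Further named genes were Slfn2 (1.36 ± 0.19) and Reg3g (1.31 ± 0.21), which rose, and the vitamin B12 receptor Cubn (-3.66 ± 0.57, from 2.35 to 0.179 CPM), Asb4 (-2.58 ± 0.44), Akp3 (-2.19 ± 0.32) and Cyp3a11 (-2.17 ± 0.36), which fell. In all, 89 genes changed, 72 higher and 17 lower. Chromosome 8 held 15 of them among its 948 tested genes (odds ratio 3.64, two-sided Fisher's exact adjusted p = 0.00372), including the Paneth cell defensin genes Defa21, Defa22 and Defa5, which rose. The count was 288 and 137 without KO NT replicate 1 and 2, 29 and 11 without KO ES replicate 1 and 2, and 24 and 25 without WT NT replicate 1 and 2. Of the 27 named genes that passed, 6 passed whichever library was left out.

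The difference of the ES effects, KO minus WT, asked whether the response differed between the genotypes. It passed for 19 genes, 17 with a lower response in KO and 2 with a higher one. Of the 17, 14 had a log2 fold change above 0 in WT and below 0 in KO. Reg1, a secreted lectin of regenerating epithelium, went from 32.9 to 111 CPM in WT and from 50.6 to 24.9 CPM in KO, a difference of -2.77 ± 0.22 (adjusted p = 0.00197). The intestinal alkaline phosphatase genes Alpi (-2.42 ± 0.31) and Akp3 (-3.60 ± 0.47) also rose in WT and fell in KO. Their KO NT levels were raised and uneven, for Akp3 18.4 to 32.6 CPM against 6.01 to 6.63 CPM in WT NT. Alpi had 64.4 and 114 CPM in KO NT replicate 1 and 2, against 49.4 and 44.2 CPM in WT NT. KO NT replicate 2 is the library with the highest mitochondrial share. In KO against WT in NT, 3 of 27 enterocyte genes were higher (3 adjusted over the list alone, adjusted p = 0.0116, and 0.696 with an estimated correlation), and the direction of the list turned without KO NT replicate 2 (adjusted p = 0.0339). The iron exporter Slc40a1 (-2.50 ± 0.28) and the transcription factor Klf10 (-1.68 ± 0.17) rose in WT and did not pass in KO. Lct (-2.18 ± 0.30), Apoa4 (-2.58 ± 0.36) and the purine enzyme Gda (-2.03 ± 0.31) complete the 8 largest. The transcription factor Sox4 (0.50 ± 0.07) and the stem cell gene Scn2b (0.76 ± 0.12) fell in WT and did not pass in KO. Raver1, next by p among higher differences, did not pass at 3.80 ± 0.59 (adjusted p = 0.0501). On GRCm38, Reg1 lies on chromosome 6 (78422711 to 78428667), and Alpi (87098002 to 87101606) and Akp3 (87124973 to 87127912) lie next to each other on chromosome 1.

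Among lists, absorptive enterocyte genes had a median difference of -1.25, with 3 of 27 lower (23 adjusted over the list alone), and immediate early genes one of -0.73, for which edgeR passed 0 of 27 (17 adjusted over the list alone, 19 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom). In NT 19 of 27 immediate early genes were already higher in KO than in WT, so their difference includes a raised start in KO. With ES in KO, Nr4a2 (-0.93 ± 0.16) was the 1 member that edgeR passed. Stem cell genes had a median difference of 0.23, with 1 of 28 higher (7 adjusted over the list alone), with Ascl2 at 0.67 ± 0.15 (adjusted p = 0.133) and Lgr5 at 0.22 ± 0.11 (adjusted p = 0.506). Of the 32 lists 20 passed the preset test and 0 the one with an estimated correlation, where the smallest adjusted p was 0.271. The goblet list's median difference was -0.05 (adjusted p = 0.0233, and 0.315 with an estimated correlation), a call lost without WT NT replicate 2 (0.0924), WT ES replicate 1 (0.101) or KO ES replicate 2 (0.144). The count of 19 genes was 1 without WT NT replicate 1 or KO ES replicate 2, 2 without WT NT replicate 2 or KO ES replicate 1, 9 without WT ES replicate 2, and 397 and 58 without KO NT replicate 1 and 2.

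Across the tested genes, the ES effects in WT and KO shared 33 risen genes, against 1.51 expected if independent (one-sided Fisher's exact p = 1.56e-36), and 2 fallen genes, against 0.236 (p = 0.0227). Reg1, Alpi and Akp3 rose in WT and fell in KO. Of the 605 genes changed in WT, 427 (70.6%) had the same sign in KO, against 54.5% of all genes, and Pearson's r across genes, which are not independent replicates, was 0.0958, and 0.452 over genes of at least 10 CPM. The number shared in the same direction, 35, was 11 and 9 without WT NT replicate 1 and 2, 20 and 21 without WT ES replicate 1 and 2, 72 and 67 without KO NT replicate 1 and 2, and 16 and 10 without KO ES replicate 1 and 2. Without WT ES replicate 1, r was 0.0252.

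KO against WT was compared in NT and in ES, where the deletion, the injection and any other difference between these animals act together. In NT, goblet cell genes were lower in KO, with 17 of 20 fallen (17 adjusted over the list alone), Tff3 by 1.04 on the log2 scale, Fcgbp by 1.02 and Muc2 by 0.75 (n = 2 each). Tuft cell genes, markers of the chemosensory cells, fell in 10 of 17 cases (14 adjusted over the list alone), with Dclk1 at -1.12 ± 0.14 and Avil at -1.37 ± 0.16. Circadian clock genes rose in 6 of 16 cases (10 adjusted over the list alone), with Per1 at 0.88 ± 0.10 and Dbp at 1.21 ± 0.27. The time of day of collection is not given, so a difference in it between WT and KO cannot be told apart from KO. With an estimated correlation the adjusted p was 0.0128 for the goblet and the tuft list and 0.0415 for the clock list. Immediate early genes rose in 19 of 27 cases (25 adjusted over the list alone), with Atf3 at 2.78 ± 0.24, Nr4a1 at 2.48 ± 0.25 and Jun at 1.24 ± 0.10 (adjusted p = 0.113 with an estimated correlation). These genes also respond to tissue handling, which could not be compared between WT and KO. Cell cycle genes rose in 18 of 37 cases (22 adjusted over the list alone, 1 lower), with Tpx2 at 0.54 ± 0.06 and Bub1 at 0.58 ± 0.07 (adjusted p = 0.0924 with an estimated correlation). Genes of PPAR signalling and fatty acid oxidation fell in 9 of 26 cases (12 adjusted over the list alone), with Cpt1a at -0.66 ± 0.06 and Slc25a20 at -0.73 ± 0.11 (adjusted p = 0.257 with an estimated correlation). MHC class II genes rose in 4 of 8 cases (5 adjusted over the list alone), with H2-Aa at 0.54 ± 0.08 (adjusted p = 0.257 with an estimated correlation). The 4 were H2-Aa, H2-Ab1, H2-Eb1 and Cd74, of which H2-Aa at least lies in the part of chromosome 17 described below. Of 7 B and plasma cell genes 1 passed, Igha, which was lower (-1.95 ± 0.36). Of 16 T and NK cell genes edgeR passed 0 (3 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom).

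The largest falls in NT among genes that met the naming rule for size, which asks for a mean of at least 1 CPM, included those of the growth factor gene Fgf1 from 167 ± 1.36 CPM to 4.69 and 5.31 CPM (-5.07 ± 0.14, adjusted p = 4.06e-08) and of the glutamate receptor gene Grm4 from 19.8 ± 0.209 to 0.580 ± 0.210 CPM (-5.11 ± 0.26). Both were as low in the ageing experiment, with Fgf1 at 7.68 to 8.56 CPM in young and 5.63 to 6.91 CPM in old (n = 3 each) and Grm4 at 0.438 ± 0.209 and 0.482 ± 0.235 CPM. For both genes the WT libraries thus stood apart from the KO and ageing libraries, with each table normalised by itself. Serpinh1 (-4.04 ± 0.82) and Park2 (-2.69 ± 0.53) also fell, and Fam71a (4.36 ± 0.52) and Egr3 (3.23 ± 0.62) rose. Stem cell genes had 3 of 28 lower (4 adjusted over the list alone) with a list adjusted p of 0.0200, and 0.696 with an estimated correlation. Lgr5 was at -0.06 ± 0.08 and Ascl2 at -0.20 ± 0.10, neither passing, and the list's direction turned without KO NT replicate 2 (adjusted p = 0.781), its call being lost without WT NT replicate 2 (0.0721). In all, 776 genes changed, 410 higher and 366 lower, and the count was 170 and 172 without WT NT replicate 1 and 2. Of the 65 named genes that passed, 27 passed whichever library was left out.

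In ES, goblet cell genes were again lower in KO, with 16 of 20 fallen (18 adjusted over the list alone), Clca1 at -2.15 ± 0.09 and Muc2 at -1.05 ± 0.06 (adjusted p = 0.0150 with an estimated correlation). Absorptive enterocyte genes fell in 19 of 27 cases and rose in 1 (24 and 1 adjusted over the list alone), with Lct at -2.47 ± 0.22, Fabp1 at -2.16 ± 0.24 and Apoa1 at -1.83 ± 0.25 (adjusted p = 0.239 with an estimated correlation). PPAR and fatty acid oxidation genes fell in 17 of 26 cases (24 adjusted over the list alone), with the fatty acid transporter Cd36 at -2.30 ± 0.32 and Ppara at -0.76 ± 0.10 (adjusted p = 0.175 with an estimated correlation). Enteroendocrine genes fell in 13 of 24 cases (19 adjusted over the list alone), with Gip at -1.57 ± 0.15 and Sst at -1.56 ± 0.21 (adjusted p = 0.174 with an estimated correlation). Tuft cell genes fell in 10 of 17 cases (11 adjusted over the list alone), with Dclk1 at -1.06 ± 0.14 (adjusted p = 0.0803 with an estimated correlation). Of 16 clock genes 7 passed and they went both ways, with Per2 (1.11 ± 0.16), Tef (1.19 ± 0.19) and Ciart (1.55 ± 0.31) higher and Npas2 (-1.13 ± 0.20) lower. Stem cell genes had 8 of 28 higher and 2 lower (8 and 2 adjusted over the list alone), with Olfm4 at 0.46 ± 0.07, Ascl2 at 0.47 ± 0.11 and Scn2b at 0.84 ± 0.08 higher and the vitamin D receptor Vdr (-0.33 ± 0.06) lower (adjusted p = 0.641 with an estimated correlation).

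Fgf1 (-4.57 ± 0.14), Grm4 (-5.22 ± 0.28), Serpinh1 (-4.83 ± 1.03) and Park2 (-4.73 ± 0.67) were the largest falls in ES by the same rule. Raver1 (2.90 ± 0.44), Tspan33 (2.40 ± 0.56) and AC124739.5 (2.08 ± 0.36) were among the largest rises. In all, 1312 genes changed in ES, 536 higher and 776 lower. The count was 793 without either WT NT library, 594 and 475 without WT ES replicate 1 and 2, 1989 and 1995 without KO NT replicate 1 and 2, and 423 without KO ES replicate 2. Of the 83 named genes that passed, 40 passed whichever library was left out. The KO effects of NT and ES shared 142 risen and 219 fallen genes, against 12.7 and 16.4 expected if independent (one-sided Fisher's exact p = 4.19e-113 and 5.90e-207).

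Chromosome 17 held more changed genes than its size. In NT 104 of its 913 tested genes changed (11.4%, against 4.09% elsewhere, odds ratio 3.03, 95% interval 2.43 to 3.76, two-sided Fisher's exact adjusted p = 9.81e-17), and in ES 120 (13.1%, against 7.25%, odds ratio 1.94, 1.59 to 2.37, adjusted p = 9.59e-08). The changed genes lay mainly before 40 Mb, a boundary chosen after the positions were seen, with 81 of 590 genes in NT and 102 of 590 in ES, against 23 and 18 of 323 after it. That part of the chromosome holds Park2 (10840384 to 12063361), Grm4 (27422387 to 27521403), Tff3 (31125306 to 31129646) and H2-Aa (34282744 to 34287823). Fgf1 lies on chromosome 18 (38838673 to 38929472), where 36 of 450 genes changed in NT (odds ratio 1.92, adjusted p = 0.0227) and 34 of 450 in ES (odds ratio 1.01, adjusted p = 1). Serpinh1 lies on chromosome 7 (99345376 to 99353239). Of the 36 mitochondrial genes 7 were higher in KO in NT (19.4%, odds ratio 5.47, 2.44 to 12.2, adjusted p = 0.0236), where KO NT replicate 2 had the highest mitochondrial share. The 7 encode ribosomal or transfer RNA. Of the 13 mitochondrial genes that encode proteins edgeR passed 0 in NT (6 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom). In ES edgeR passed 0 of the 36 (two-sided Fisher's exact adjusted p = 0.565).

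**Figure D3:**
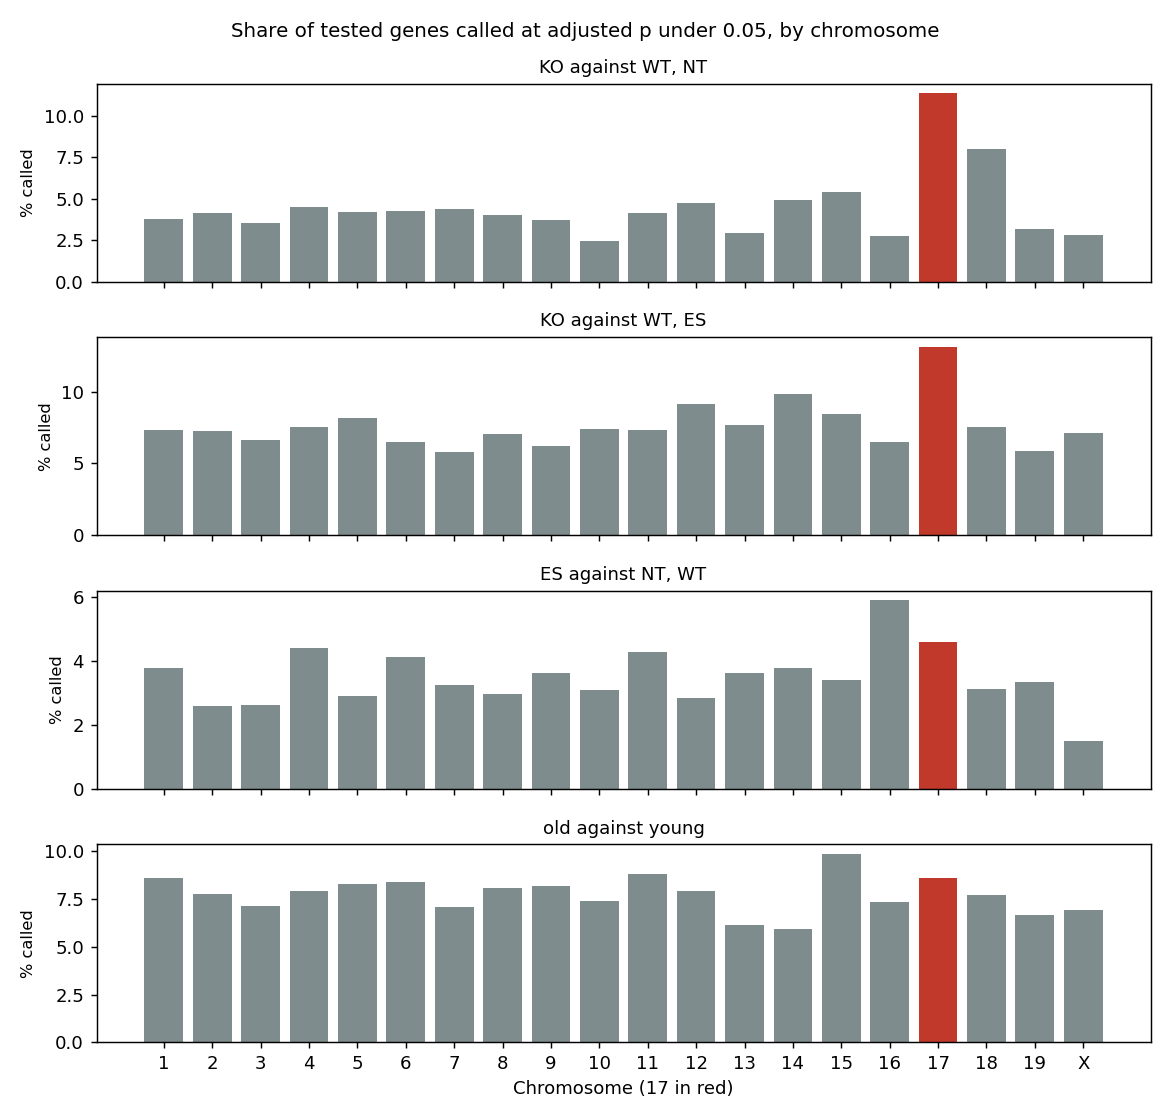
Percent of tested genes that changed, by chromosome, in both KO comparisons, in ES in WT and in old against young. Of the chromosomes drawn (1 to 19 and X), chromosome 17, in red, is highest in both KO comparisons, at 11.4% in NT and 13.1% in ES.

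Old against young asked what age changed in stem cells. Genes of T and natural killer (NK) cells were higher in old, with 15 of 16 risen (15 adjusted over the list alone). Gzma, a granule protease of killer cells, went from 12.6 ± 2.82 to 71.5 ± 5.27 CPM (n = 3 each, 2.51 ± 0.13, adjusted p = 2.37e-06), and Cd8a rose by 2.63 ± 0.19 and Itgae, the integrin of T cells within the epithelium, by 1.87 ± 0.13. All 8 MHC class II genes, which present antigen, rose (8 adjusted over the list alone), with Cd74 going from 190 ± 17.6 to 692 ± 146 CPM (1.87 ± 0.13) and H2-Aa from 24.0 ± 4.57 to 166 ± 48.9 CPM (2.79 ± 0.20). Tuft cell genes fell in 10 of 18 cases (15 adjusted over the list alone), Dclk1 from 46.8 ± 4.14 to 17.8 ± 0.601 CPM (-1.39 ± 0.09, adjusted p = 0.0769 for the list with an estimated correlation). Of genes listed to mark RNA of other origin, the 4 tested haemoglobin genes of red cells rose (4 by DESeq2, 3 by limma-voom), their sum being 0.398 to 0.896 CPM in young and 2.51 to 6.24 CPM in old. Of 2 genes listed for pancreatic acinar cells Cela1 rose (0.93 ± 0.18) and Clps fell (-0.63 ± 0.08), both also passing by DESeq2 and limma-voom. Clps also rose with ES in KO (0.53 ± 0.09). Paneth cell genes moved in the same directions in these 2 comparisons, so the origin of Clps RNA was not settled. Of 5 sex-linked genes 1 passed by each of the 3 tools, Eif2s3y (-0.45 ± 0.08), and Xist did not (-0.38 ± 0.25, adjusted p = 0.427).

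The clock genes moved in opposite directions, with 9 of 16 lower and 2 higher (10 and 2 adjusted over the list alone). Dbp (-2.73 ± 0.21), Tef (-2.26 ± 0.09) and Per2 (-1.10 ± 0.08) fell, and Arntl (1.36 ± 0.09) and Npas2 (1.14 ± 0.11), which peak at the other end of the daily cycle, rose. The time of day of collection is not given in the sources used here. Immediate early genes, which respond within minutes to stimuli and to tissue handling, rose in 21 of 27 cases (25 adjusted over the list alone), with Atf3 at 1.55 ± 0.09, Dusp1 at 1.05 ± 0.07 and Egr1 at 0.88 ± 0.06. With an estimated correlation the adjusted p was 0.0405 for T and NK cell genes, 0.0408 for MHC class II, 0.0337 for clock and 0.0405 for immediate early genes.

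Hormone cell genes rose in 11 of 26 cases (18 adjusted over the list alone), with Insm1, a factor of endocrine differentiation, at 0.91 ± 0.12 and Chgb at 0.72 ± 0.08 (adjusted p = 0.101 with an estimated correlation). PPAR and fatty acid oxidation genes rose in 11 of 26 cases (16 adjusted over the list alone), with Pdk4, which limits glucose oxidation, going from 1.48 ± 0.445 to 22.4 ± 2.30 CPM (3.92 ± 0.18) and Angptl4 at 2.70 ± 0.20 (adjusted p = 0.0778 with an estimated correlation). Glucocorticoid targets, which share Pdk4 and Angptl4 with that list, rose in 7 of 17 cases and fell in 1 (11 and 1 adjusted over the list alone), with Zbtb16 at 3.93 ± 0.24 and Fkbp5 at 0.48 ± 0.08 (adjusted p = 0.0778 with an estimated correlation). Genes of the unfolded protein response rose in 10 of 23 cases (14 adjusted over the list alone), with Herpud1 at 0.82 ± 0.08 and Chac1 at 1.83 ± 0.32 (adjusted p = 0.123 with an estimated correlation). Paneth cell genes fell in 7 of 20 cases (11 lower and 4 higher adjusted over the list alone), with Ang4 at -1.78 ± 0.09 and Mptx1 at -2.67 ± 0.22 (adjusted p = 0.282 with an estimated correlation).

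Among p53 targets 5 of 25 rose (5 adjusted over the list alone), with Trp53inp1 at 1.17 ± 0.10, Eda2r at 1.43 ± 0.23 and Cdkn1a at 0.41 ± 0.11 (adjusted p = 0.0639 for the list with an estimated correlation). Senescence genes rose in 3 of 16 cases (4 adjusted over the list alone), which were the T cell chemokine Ccl5 (1.97 ± 0.19), also in the T and NK cell list, and the cell cycle inhibitors Cdkn1b (0.24 ± 0.06) and Cdkn1a (adjusted p = 0.0983 with an estimated correlation). The p38 pathway had 0 of 14 passing in edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom). Stem cell genes did not move as a list (adjusted p = 0.594), with 2 of 28 higher and 3 lower (3 and 5 adjusted over the list alone), Ascl2 falling from 32.4 ± 4.04 to 21.0 ± 2.22 CPM (-0.62 ± 0.11), Scn2b at -0.44 ± 0.09 and Vdr at 0.29 ± 0.05. Lgr5 was at -0.25 ± 0.08 (adjusted p = 0.0856), Olfm4 at 0.05 ± 0.08 and Mki67 at 0.02 ± 0.08. Goblet cell genes went both ways, 3 of 20 higher and 3 lower (4 and 4 adjusted over the list alone, adjusted p = 0.916), with Zg16 at 1.42 ± 0.16 and Fcgbp at 0.64 ± 0.07 higher and Clca1 at -1.17 ± 0.11 and Retnlb at -3.73 ± 0.43 lower.

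**Figure D4:**
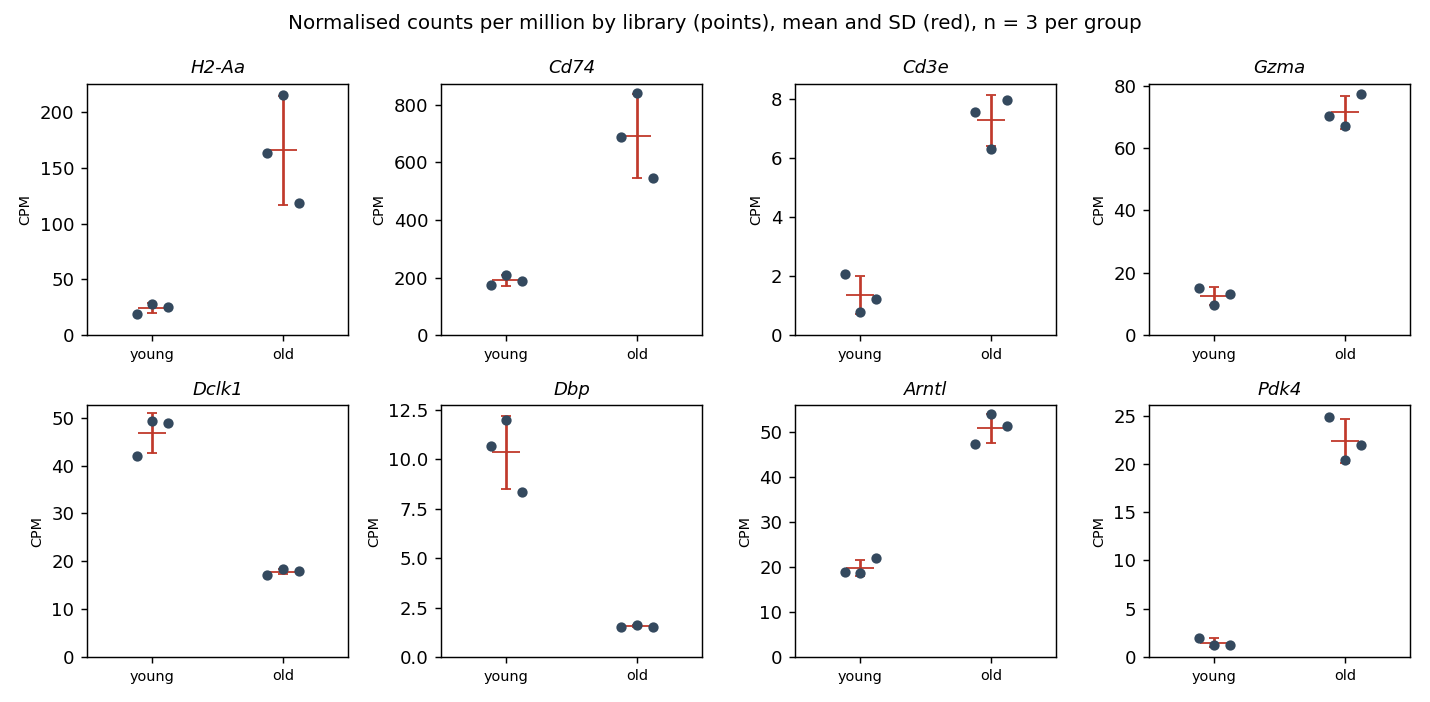
CPM of 8 genes in each young and old library, with mean and standard deviation (n = 3 per group). Cd74, Gzma, Arntl and Pdk4 are higher in each old library than in any young one, and Dclk1 and Dbp are lower.

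By the naming rule, the largest rises were those of Klrd1, an NK cell receptor (4.44 ± 0.38, from 0.224 to 4.90 CPM), Ddr2 (4.14 ± 0.53), Cd200r1 (4.07 ± 0.69), P2ry10 (4.01 ± 0.55), Zbtb16, Pdk4, Zbed6 (3.89 ± 0.53), whose position lies within another gene on the same strand, and Apol7b (3.42 ± 0.38). Among the largest falls were those of Fn1 (-4.65 ± 0.72), Pla2g4c (-3.74 ± 0.38), Retnlb, Gsdmc (-3.35 ± 0.50), Amotl1 (-3.17 ± 0.26), Igf2bp3 (-3.12 ± 0.36) and Zcchc3 (-3.02 ± 0.59). On GRCm38, Klrd1 lies on chromosome 6 (129591782 to 129598775), Cd74 on chromosome 18 (60803848 to 60812652), Dclk1 on chromosome 3 (55242364 to 55539068), Dbp on chromosome 7 (45705088 to 45710203) and Zbtb16 on chromosome 9 (48654297 to 48836222). In all, 1318 of 16807 genes changed, 743 higher and 575 lower, 459 at least 2-fold. The count was 811 and 647 without young replicate 1 and 2 and 652 without old replicate 1. Of the 93 named genes that passed, 73 passed whichever library was left out.

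The last comparison set ES in WT beside age, the link named in the series title. Genes that rose with ES in WT rose in old more often than independence gives, 68 against 15.9 (one-sided Fisher's exact p = 8.64e-25), and 33 fell in both, against 8.10 (p = 6.42e-12). Fcgbp (0.96 with ES, 0.64 in old), Zg16 (1.32 and 1.42), Gip (1.18 and 1.30), Zbtb16 (2.48 and 3.93), Il18 (1.08 and 0.76) and Cd74 (0.52 and 1.87) rose in both, and Ascl2 (-0.74 and -0.62) and Scn2b (-0.75 and -0.44) fell in both. Another 20 genes rose with ES and fell in old, against 12.4 expected (one-sided Fisher's exact p = 0.0247), among them Retnlb (3.50 and -3.73), Clca1 (1.60 and -1.17) and Ang4 (0.55 and -1.78), and 6 went the other way. Genes that rose with ES in KO overlapped age in both directions. Of these, 10 rose in old, against 3.07 expected (one-sided Fisher's exact p = 0.000898), and 11 fell, against 2.38 (p = 2.26e-05 by the same test). Among genes that fell with ES in KO, 2 fell in old and 1 rose. Of 602 genes changed by ES in WT and tested in both tables, 425 (70.6%) had the same sign in old, against 57.3% of all genes. Pearson's r across genes was 0.0465, Spearman's 0.144, and Pearson's r 0.237 over genes of at least 10 CPM. The 101 genes shared in the same direction were 13 and 10 without WT NT replicate 1 and 2, 32 and 31 without WT ES replicate 1 and 2, 180 and 181 without KO NT replicate 1 and 2, 57 and 43 without young replicate 1 and 2, and 52 without old replicate 1.

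The 723 genes higher in old, tested as a set, were higher with ES in WT, with a median of 0.11 (adjusted p = 4.75e-07, and 0.0340 with an estimated correlation). With ES in KO the set did not pass (median 0.00, adjusted p = 0.665), and the difference, KO minus WT, had a median of -0.08 (adjusted p = 3.79e-05, and 0.0363 with an estimated correlation). In ES the set was lower in KO than in WT (median -0.08, adjusted p = 0.000395, and 0.0398 with an estimated correlation). In NT it did not pass (median -0.05, adjusted p = 0.748). The passing comparisons all use the same WT ES libraries, so they are not independent of each other. The 562 genes lower in old had a median of -0.07 with ES in WT (adjusted p = 0.0279, and 0.352 with an estimated correlation). That call was lost without WT NT replicate 1 (0.0603), WT ES replicate 2 (0.176), KO NT replicate 1 (0.0735) or 2 (0.0506), young replicate 1 (0.410), 2 (0.869) or 3 (0.0562), and old replicate 1 (0.939) or 2 (0.775). Their difference between genotypes had a median of 0.12 (adjusted p = 0.00136, and 0.210 with an estimated correlation), a call lost without KO NT replicate 1 (0.0735), young replicate 2 (0.151) or old replicate 1 (0.0823).

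**Figure D5:**
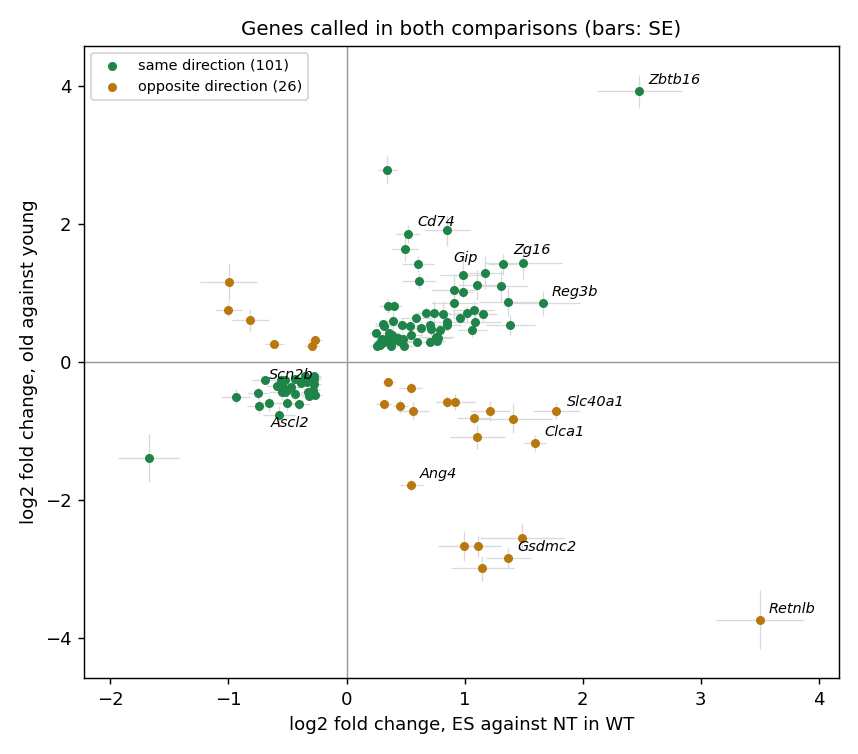
Log2 fold change with ES in WT (horizontal) and in old against young (vertical) for genes that changed in both comparisons, with standard errors. The 101 genes that share a direction are green and the 26 that do not are orange.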

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

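The test of the Cd3 genes and Ptprc, the test of the B cell list alone, the chromosome 17 odds ratio as a test of the deletion, the 40 Mb boundary and the comparison with the ageing libraries were chosen after the result was seen. The excess on chromosome 17 was seen before its repeat in ES was tested.

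A test of the difference of the ES effects, KO minus WT, singled out 19 genes. Lower responses in KO were found for Akp3 (-3.60), Reg1 (-2.77), Apoa4 (-2.58), Slc40a1 (-2.50), Alpi (-2.42), Lct (-2.18), Gda (-2.03), Klf10 (-1.68), Xdh (-1.64), Per1 (-1.24), Slc9a3 (-1.13), Clca1 (-1.05), Rassf1 (-0.87), Midn (-0.86), Myo7a (-0.80), Bmp3 (-0.61) and Dmbt1 (-0.56). Higher ones were found for Sox4 (0.50) and Scn2b (0.76). Without WT NT replicate 1 or KO ES replicate 2 the count was 1, without WT NT replicate 2 or KO ES replicate 1 it was 2, without WT ES replicate 2 it was 9, and without KO NT replicate 1 and 2 it was 397 and 58.

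The same test singled out 20 lists, none with an estimated correlation. The median differences that held without each library in turn were 0.23 for stem cell, 0.25 for Wnt target, -1.25 for absorptive enterocyte, -0.73 for immediate early, -0.29 for heat shock, -0.15 for glucocorticoid target, -0.13 for PPAR and fatty acid oxidation, -0.13 for nuclear-encoded respiratory chain and 0.77 for B and plasma cell genes. In NT, 19 of 27 immediate early and 3 of 18 heat shock genes were higher in KO than in WT, so these differences include a raised start in KO. Of 7 B and plasma cell genes, the 1 that passed in NT was Igha, lower in KO (-1.95 ± 0.36). For Igha the difference thus includes a lowered start in KO. Calls lost without KO NT replicate 1 were those of Paneth (0.24, adjusted p = 0.0981) and antimicrobial genes (-0.17, 0.0981). Interferon response genes (0.10) lost theirs without WT ES replicate 2 (0.452) or KO NT replicate 2 (0.0724), and unfolded protein response genes (-0.15) without KO NT replicate 2 (0.0538) or KO ES replicate 1 (0.352). The goblet list (-0.0550) lost its call without WT NT replicate 2 (0.0924), WT ES replicate 1 (0.101) or KO ES replicate 2 (0.144), the tuft list (0.29) without WT NT replicate 1 (0.0546), KO NT replicate 2 (0.354) or KO ES replicate 1 (0.115), and the enteroendocrine list (-0.29) without WT ES replicate 1 (0.101), KO NT replicate 2 (0.153) or KO ES replicate 2 (0.153). T and NK cell genes (0.34) lost it without WT NT replicate 1 (0.0546), WT ES replicate 1 (0.101), KO NT replicate 1 (0.266) or KO ES replicate 2 (0.175), and antioxidant genes (-0.11) without WT NT replicate 2 (0.0682), WT ES replicate 2 (0.102), KO NT replicate 2 (0.400) or KO ES replicate 1 (0.276). Clock genes (-0.20) lost it without WT NT replicate 1 (0.0698) or 2 (0.0563), WT ES replicate 1 (0.0908) or 2 (0.0565), KO NT replicate 2 (0.0873) or KO ES replicate 1 (0.130), and fetal-like and YAP target genes (-0.39) without WT NT replicate 1 (0.0502) or 2 (0.0563), WT ES replicate 1 (0.0850) or 2 (0.0664), KO NT replicate 1 (0.0981) or KO ES replicate 1 (0.132).

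Both ageing sets differed as well, genes higher in old by a median of -0.0818 (adjusted p = 0.0363 with an estimated correlation) and genes lower in old by 0.12 (adjusted p = 0.210 with an estimated correlation, 0.0926 by fry). The latter call was so lost, and also without KO NT replicate 1 (adjusted p = 0.0735), young replicate 2 (0.151) or old replicate 1 (0.0823).

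With ES in WT, 15 of 20 goblet cell genes rose and 15 of 28 stem cell genes fell (adjusted p = 0.169 for the stem cell list with an estimated correlation), which a lower share of stem cells in the sort could give if it raised every other lineage alike. The tuft list had a median of 0.09 (0.0925), with a 95% interval over members from -0.10 to 0.33 that lies below the goblet interval of 0.44 to 0.91, which argues against an even rise of all lineages. The condition written beforehand also asked for a list median at or below 0, and no list met that part, so the prediction as written was not fulfilled. Paneth (0.27), enteroendocrine (0.58) and enterocyte genes (0.53) had medians above 0, so a sort with more secretory and absorptive cells but not more tuft cells stays open, as does a response to ES within the cells. These values are for WT. With ES in KO the tuft median was 0.36 (0.24 to 0.50), the goblet median 0.70 (0.54 to 0.78) and the enterocyte median -0.58 (-1.20 to -0.19).

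T and NK cell genes and MHC class II genes were higher in old, which T, NK or antigen-presenting cells among the sorted cells could give. A gate on EGFP from Lgr5 is meant to leave such cells out, but how fully it did so was not measured here. Cd3d, Cd3e, Cd3g and Ptprc had a median of 2.01, from 1.51 to 2.47, but they belong to a list already seen to rise, so this decides nothing and T or NK cells stay open, with list sums of 43.1 to 64.1 CPM in young and 210.1 to 252 CPM in old, with Ccl5 also in the senescence list. B cells as the source of MHC class II are argued against by a B and plasma cell median of -0.25 (interval -0.97 to 0.17) against 1.80 (1.31 to 2.01), with sums of 10.3 to 11.9 CPM in young and 8.30 to 9.56 CPM in old. Of 9 myeloid genes 3 rose, Itgax by 2.94 ± 0.35, Fcer1g by 1.86 ± 0.35 and Itgam by 0.87 ± 0.20. The myeloid list had a median of 0.87 (-0.11 to 2.20), an interval wide enough to leave myeloid cells open, with sums of 49.7 to 74.3 and 84.7 to 117 CPM against 318 to 389 and 1059 to 1686 CPM for MHC class II. Age acting on the stem cells themselves was not tested apart from these, and the 10 splits of the 6 ageing libraries are too few for a share under 0.05, with 1318 genes in the real split, 1 split as large, itself, and 1 gene in the highest of the others.

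Genes changed by KO were in excess on chromosome 17, with an odds ratio of 3.03 in NT, a value that is the pattern itself and so decides nothing about loss of Chrm3 or the injection. A segment of another strain that differs between WT and KO animals could give it, and 61.5% of the chromosome 17 genes changed in NT changed the same way in ES, against 44.2% elsewhere (odds ratio 2.01, interval 1.32 to 3.06, one-sided Fisher's exact p = 0.000699). Of the genes changed the same way in both KO comparisons, 45 of 56 before 40 Mb on chromosome 17 had levels in the ageing libraries nearer to KO than to WT, against 106 of 286 on other chromosomes, with tables normalised separately. Before 40 Mb the median absolute log2 distance of the ageing levels was 0.155 to KO and 0.690 to WT. No deletion or injection is recorded for the ageing mice, so these values argue against loss of Chrm3 or tamoxifen as the source for most of these genes. The 4 such genes after 40 Mb were all nearer to KO too, with median distances of 0.169 to KO and 0.614 to WT. Fgf1 on chromosome 18 had 5.63 to 8.56 CPM in the ageing libraries, near its 4.69 to 7.15 CPM in KO. For the other changed genes, loss of Chrm3 and tamoxifen both stay open. No genotype of the segment was read from sequence, so its origin stays open, and H2-Aa and Tff3 lie in it.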

How the results depend on the processing

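Leaving out chromosome 17, or the T and NK cell, MHC class II, clock and immediate early lists, was chosen after the data were seen and removes too few genes to move a count by 1.5 times, leaving 563 genes for ES in WT, 84 for ES in KO, 672 for KO in NT, 1192 for KO in ES and 1263 for age. RLE size factors (22 results) and a 1 CPM filter (6 counts) kept each result on its side of the threshold or within 1.5 times. A library left alone in its group was assumed to vary like the others. The cause was not tested for any shift below, except that fewer libraries or a changed threshold alter a count by construction.

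Genes changed by ES in WT numbered 114 with no filter, 970 with the replicate block, 1043 by DESeq2, 86 at 2-fold, 1223 at an adjusted p under 0.1, 1875 with only the 2 groups, and 35 to 1263 leaving out a library. For ES in KO they were 8, 206, 226, 24, 188 and 24 in that order, and 11 to 288. For KO in NT they were 317 with no filter, 209 at 2-fold, 1262 at 0.1, and 170 to 937, and for KO in ES 593, 291, 2178, and 423 to 1995. For the difference of the ES effects they were 0 with no filter (edgeR, with 1999 genes at an unadjusted p under 0.05 in the filtered fit), 11 by the older quasi-likelihood test, 104 with the block, 211 by DESeq2, 8 by limma-voom, 12 at 2-fold, 49 at 0.1, and 1 to 397. For old against young they were 666 with no filter, 2019 with the block, 459 at 2-fold, 1991 at 0.1, and 647 to 1516.

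Genes shared by ES in WT and age numbered 240 at 0.1, 718 at an unadjusted p under 0.05, 203 by DESeq2, 234 with the block, and 10 to 181 leaving out a library, and r was 0.144 by Spearman, 0.237 over genes of at least 10 CPM. Those shared by ES in WT and in KO were 72, 435, 91, 67, and 9 to 72, with r 0.452 over genes of at least 10 CPM and 0.0252 to 0.0945 leaving out a library. For genes lower in old, the adjusted p in ES in WT was 0.352 with an estimated correlation and 0.000178 to 0.939 leaving out a library, in the difference 0.210 and 2.83e-06 to 0.151, in KO in ES 0.00690 with the block and 0.00209 to 0.972, in ES in KO 0.00319 to 0.532, and in KO in NT 0.0182 to 0.532. The fry test of any change gave 0.111 for this set in ES in WT and 0.0926 in the difference. Chrm3 in KO in ES was at -0.67 with no filter, not passing, and -0.90 to -0.47 leaving out a library.

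Of 101 list calls, 10 held with an estimated correlation and 100 each with the block and with RLE. By fry, which tests for any change and not for a difference from other genes, 50 of these lists passed in the same direction. The direction turned for the list intestinal stem cell in ES in KO without KO NT replicate 1 (adjusted p = 0.764, and 7.10e-12 without KO NT replicate 2). It turned for the list intestinal stem cell in KO in NT without KO NT replicate 2 (0.781, and 1.73e-06 without KO NT replicate 1) and for the list absorptive enterocyte in KO in NT without KO NT replicate 2 (0.0339, and 2.48e-17 without KO NT replicate 1). These pairs of values are the highest and lowest leaving out a library. No named gene turned under the settings tried. Of 340 named gene calls, 141 were lost with no count filter, 3 with RLE and 3 by DESeq2. The labels give libraries the same numbers without saying that they were paired. Deviations of same-numbered libraries correlated by -0.00832 to 0.103 in the Chrm3 table and by 0.00454, 0.0837 and 0.0802 in the ageing table, where young replicate 1 went best with old replicate 2 (0.0269), so the block is given here alone.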

Other observations

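With ES in WT, reserve stem cell genes fell in 2 of 7 cases (3 adjusted over the list alone), Hopx at -0.33 ± 0.07 and Mex3a at -0.55 ± 0.11 (adjusted p = 0.169 with an estimated correlation). Genes of the unfolded protein response rose in 2 of 23 cases (13 adjusted over the list alone), Herpud1, which helps clear misfolded proteins, at 0.41 ± 0.06 and Ern2, the stress sensor of mucus-making cells, at 0.47 ± 0.08 (adjusted p = 0.260 with an estimated correlation). MHC class II genes rose in 2 of 8 cases (4 adjusted over the list alone), Cd74 at 0.52 ± 0.10 and H2-Aa at 0.35 ± 0.08 (adjusted p = 0.338 with an estimated correlation).

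In old against young the interferon response genes split, 7 of 46 higher and 7 lower (12 and 14 adjusted over the list alone, adjusted p = 0.534). The lower ones included Usp18 (-1.02 ± 0.18), Irf7 (-0.64 ± 0.11) and Oasl2 (-0.64 ± 0.11), typical of the type I response, and the higher ones Gbp8 (1.32 ± 0.22) and the antigen-processing genes Psmb8 (0.84 ± 0.17), Tap2 (0.61 ± 0.13) and Nlrc5 (0.56 ± 0.12). Heat shock genes rose in 5 of 17 cases (5 adjusted over the list alone), Hsph1 at 0.64 ± 0.06 and Dnajb1 at 0.44 ± 0.08 (adjusted p = 0.172 with an estimated correlation). Members of both paragraphs were picked as examples after their values were seen.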
